A study of Mus musculus with 2 samples.

How the data were processed

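Midbrain tissue of mouse embryos (embryonic day 15.5, strain B6NCrl, healthy, both sexes pooled) was immunoprecipitated with an antibody against H3K27me3 and sequenced, per the labels. The labels name 2 biological replicates of 1 group, each with 2 technical replicates that the deposited lists combine. The 4 peak lists were used, all in narrowPeak format on mm10 per the deposited file descriptions: 1 for each replicate, 1 called on both replicates pooled, and 1 of replicated peaks derived from these. The peak caller, the aligner, the rule for a replicated peak and the control libraries behind each list are not given in the sources used here. The deposited descriptions do list 1 more input file for the replicate 1 list than for the replicate 2 list.

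Each peak's enrichment is a ratio, a fold over control as deposited by the authors in the narrowPeak column for signal. The p-value and q-value of each peak are the authors' deposited −log10 values. The fold, p and q are the authors' own values for the peak and were used only to describe, rank or filter peaks within a list. The lowest −log10 p was between 2.02 and 2.03 in every list, a loose threshold, so weak peaks are numerous. A narrow-peak format cuts a broad mark into pieces, so covered length is given beside peak numbers. Read depth is unknown and no interval that needs it is given. With 2 replicates, a mean ± SD describes the spread between these pools alone.

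Gene positions came from GENCODE M21, on the same build as the peak lists, and base composition from the GRCm38 reference sequence. The 21911 protein-coding genes were each given 1 start, the annotated 5′ end. That start can lie far from the start most used in this tissue, so marking at any annotated transcript start was also recorded. A promoter was the start and 1 kb to each side, and it was called marked when a replicated peak overlapped it by at least 1 bp. The covered share of a gene is the percentage of the 5 kb to each side of its start that lies under peaks. Promoters were called CpG-rich when the 0.5 kb to each side of the start had a CpG observed over expected of at least 0.6 and a GC fraction of at least 0.5. Domains were replicated peaks merged when no more than 3 kb apart.

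Overlap between replicates and location relative to genes were tested against 1000 circular shifts of the peaks within the sequenced span of each chromosome (2661.9 Mb in all), which keep peak widths and clustering. The overlap test was one-sided and the location test two-sided. The correlation of fold enrichment was Spearman's, across overlapping peaks, without a p-value. Gene lists were tested by two-sided Fisher's exact test against all other protein-coding genes with Benjamini-Hochberg adjustment over 31 lists, at a threshold of 0.05. The lists, fixed before the data were examined, were Hox clusters, midbrain patterning, dopaminergic and other transmitter identity, forebrain patterning, hindbrain and spinal cord patterning, mesoderm regulators, endoderm regulators, microglia and immune markers, vascular and blood markers, meningeal and neural crest markers, pan-neuronal, neural progenitor, glial, housekeeping, Polycomb and H3K27 demethylase genes, germline, imprinted, CDK inhibitors, olfactory receptors, the Fox, Sox, Tbx, Pax, Gata, Lhx and Lmx, Nkx, Irx and sine oculis homeobox (Six1 to Six6) families, and Wnt, Fgf, and Bmp and Gdf ligands. Some genes are in several lists.

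Named genes followed a rule also fixed before the data were examined. From each list it took up to 3 marked members with the largest covered share and up to 2 unmarked members in alphabetical order, and it allowed every member of the midbrain, transmitter, Polycomb and CDK inhibitor lists. It added genes starting in the 10 widest domains, the promoter with the highest fold and the 10 most covered genes. Genes named outside this rule are said to have been chosen after their values were seen.

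Alternatives were a reciprocal overlap of 50%, a −log10 q of at least 2, a fold of at least 3, equal numbers of peaks from each replicate, promoters of 0.5 or 2.5 kb to each side, 50% coverage of the promoter window, any transcript start, pooled peaks, the peaks of either replicate alone, merging distances of 1 and 10 kb, 1 gene per cluster of genes within 100 kb, and CpG-rich promoters alone. Limiting the list to replicated peaks that overlap both replicates, and leaving out chromosome X, were added after seeing the data.

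The procedures were tested on simulated data. Of 40 pairs of unrelated peak lists, 5% had an overlap p of 0.05 or less. A planted overlap of 30.4% was recovered as 30.4%. The unrelated lists were circular shifts, like those of the test, and other overlapping peaks were removed from the planted list. These results therefore check the code and not the assumptions. Of 50 simulated lists of 20 genes with 60% marked against 20% of the background, 82% were called by Fisher's exact test with adjustment. None of 200 unchanged lists was called. The simulated genes were independent, so the effect of neighbouring genes was not tested. The simulated background of 20% was also above the 12.6% of real promoters marked. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.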

Results

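H3K27me3, the histone methylation mark that the Polycomb repressive complex places over silent developmental genes, was mapped by chromatin immunoprecipitation and sequencing in the midbrain of B6NCrl mouse embryos at embryonic day 15.5. The labels describe 2 biological replicates of 1 group. Midbrains of 78 embryos were pooled in replicate 1 and midbrains of 62 embryos in replicate 2, with both sexes in each pool. A peak in such a pool does not show which cells carried the mark, and expression was not measured. There was no other tissue, stage or genotype, so the comparisons were between the replicates and between the mark and the genes and regions of the genome (mm10). Replicate 1 had 70533 peaks over 28.1 Mb, which is 1.06% of the sequenced span, and replicate 2 had 33553 peaks over 15.0 Mb, or 0.564%. The median widths were 263 and 286 bp. Read depth is unknown, because the files hold peaks without read counts, so no counting interval is given.

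The first question was how far the biological replicates carried the mark at the same places. Both replicates marked the promoters of all 39 Hox genes, which set position along the body axis, and both marked Nkx2-2, Foxa2, Wnt1, Pax5 and Fgf8 among the genes that pattern the midbrain. The Hoxc cluster was 93.6% covered by peaks in replicate 1 and 90.7% in replicate 2, and the Hoxb cluster 80.8% and 72.5%. Genome-wide, 23162 peaks of replicate 2 (69.0%) overlapped a peak of replicate 1 by at least 1 bp, and 21173 peaks of replicate 1 (30.0%) overlapped a peak of replicate 2. With replicate 2 shifted along each chromosome these shares averaged 2.21% and 1.05%. The Jaccard index, the shared length over the combined length, was 0.323 against 0.00416 after shifting. Each value exceeded all 1000 shifts (one-sided permutation p = 0.001, the smallest they can give).

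Strong peaks were shared far more often than weak ones. In the strongest 10% of each list by p-value, 99.2% of replicate 2 peaks and 89.3% of replicate 1 peaks were overlapped by the other replicate. In the weakest 10% the shares were 51.1% and 11.3%. On chromosome X, 15.7% of its 9535 replicate 1 peaks were overlapped by replicate 2, whereas on the autosomes together the share was 32.3%. In the other direction 62.4% of its replicate 2 peaks were overlapped, just under the 62.8% to 73.8% of the autosomes. Across the 21173 overlapping pairs the authors' fold enrichments had a Spearman correlation of 0.414, with a 95% interval of 0.396 to 0.432 from resampled 1 Mb blocks. This correlation is across peaks, which are not independent replicates. With the same number of peaks from each list, the share of replicate 1 peaks overlapped was 47.1% and that of replicate 2 peaks 55.4%. When each peak of a pair had to cover 50% of the other, the shares were 15.5% and 32.7%.

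**Figure D1:**
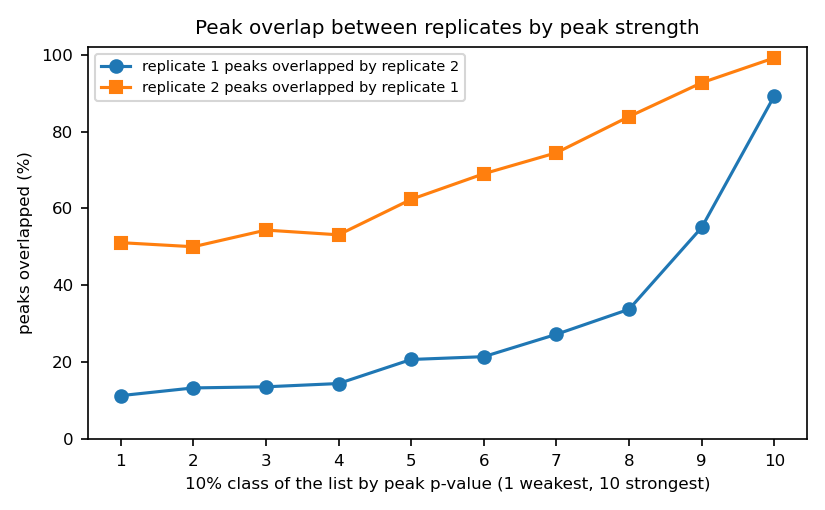
Share of peaks (%, vertical axis) overlapped by at least 1 bp by the other replicate, by 10% class of each list in order of the authors' peak p-value (horizontal axis, class 10 strongest); blue circles are replicate 1 peaks and orange squares replicate 2 peaks. The share reaches 89.3% and 99.2% in the strongest class, from 11.3% and 51.1% in the weakest.

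The deposited list of replicated peaks was used as the tissue's set of marked regions. The peak with the highest fold enrichment, 10.4 by the authors' values, spanned 30956255 to 30959937 on chromosome 6 and covered the 5′ end and most of Klf14, which encodes a Kruppel-like transcription factor. Among the 10 strongest peaks by p-value were also peaks in the Hoxb and Hoxc clusters, a peak over the whole of Helt (chromosome 8, 46291046 to 46297270), which directs GABAergic neuron identity in the midbrain, and a peak of 18140 bp on chromosome 19 (37683261 to 37701400) that held the gene starts of Cyp26c1 and Cyp26a1. The Cyp26 enzymes degrade retinoic acid. The peak at rank 3 lay at the noncoding gene 1810010K12Rik, which like both Cyp26 genes was picked out after its values were seen, and those at ranks 4, 6 and 9 had no annotated gene start within 1 kb. The list held 27808 peaks over 20.7 Mb with a median width of 466 bp. Chromosome Y had no peak in any list.

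Each of the 27808 replicated peaks was identical in position to a peak called on the pooled replicates, of which 41.5% were kept. Peaks of both replicates overlapped 17760 of them (63.9%). Another 7503 overlapped a peak of replicate 1 alone, 1738 a peak of replicate 2 alone, and 807 overlapped neither. The 10048 peaks without overlap in both were narrower, with a median of 325 bp against 615 bp, and 20.6% of them lay on chromosome X against 8.01% of the rest. Location, marked promoters, gene list tests and domains were therefore repeated with the 17760 peaks, a choice made after seeing the data.

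Chromosome X had 3488 of the replicated peaks (12.5%) and 7.51% of their length. Replicated peaks covered 0.927% of X and 0.779% of the whole sequenced span. By the replicates' own peaks the values were 1.776% and 1.055% in replicate 1, and 0.4035% and 0.5636% in replicate 2. The replicated X peaks were gathered in a few regions. The 17 fullest of its 169 bins of 1 Mb held 78.0% of them, where on the autosomes the fullest 10% of bins held 39.7% to 69.0%. The replicates' own X peaks were gathered in the same way, at 67.4% and 77.0%, against at most 55.0% and 69.3% on an autosome. The fullest bin of the replicated list, from 103 to 104 Mb with 310 peaks, holds Xist, the RNA gene that starts X inactivation, and was picked out after its values were seen. It held 524 peaks in replicate 1 and 237 in replicate 2. These X counts were made after seeing the data.

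**Figure D2:**
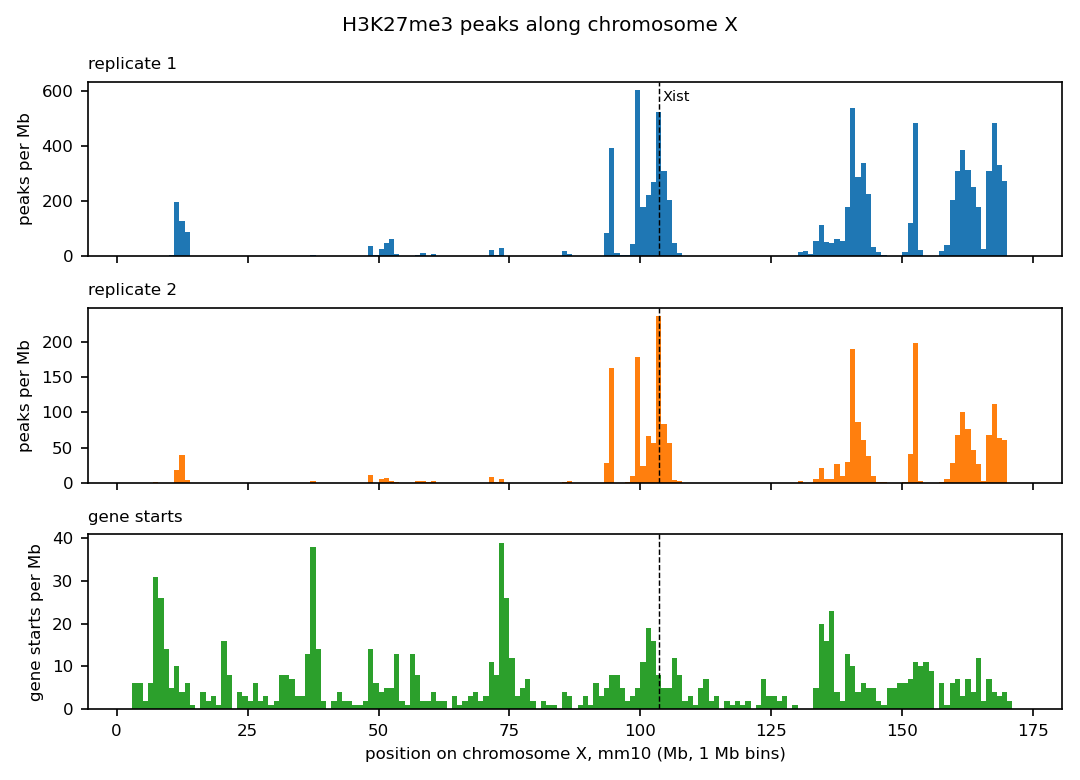
Peaks per 1 Mb bin of chromosome X in replicate 1 (top) and replicate 2 (middle) and protein-coding gene starts per bin (bottom), against position on mm10 in Mb; each panel has its own vertical scale and the dashed line marks Xist. Both replicates have their peaks in the same few regions, and 49.1% of the bins have no peak in replicate 1.

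The next question was where the mark lay relative to genes. Promoters, taken as 1 kb to each side of the 5′ end of a protein-coding gene, held 13.4% of the marked sequence, 7.92 times the average of the shifted peaks. Exons outside promoters held 9.05%, 2.59 times that average. Intergenic sequence held 43.7% of the marked bases but only 0.751 of the shifted average. For these classes the two-sided permutation p was 0.002, the smallest that 1000 shifts can give. Introns held 33.8%, 0.923 of the shifted average (two-sided permutation p = 0.0759). This p fell to 0.00799 without chromosome X and to 0.0240 with the peaks of replicate 2 alone, and over all alternatives it ranged from 0.002 to 0.156. Of the replicated peaks, 4175 (15.0%) touched a promoter.

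Replicated peaks marked the promoters of 2750 of 21911 protein-coding genes (12.6%). By their own peaks, replicate 1 marked 3553 (16.2%) and replicate 2 marked 2616 (11.9%), a mean of 14.1% ± 3.02 (SD, n = 2). Both replicates and the replicated list had 2279 of these genes in common. Marked promoters made up 14.9% of the 9725 CpG-rich promoters and 10.7% of the 12186 others. In replicate 1 these shares were 17.2% and 15.4%, and in replicate 2 they were 14.0% and 10.3%. Only 1367 promoters were covered over at least 50% of their window and 1782 held a peak with a fold enrichment of at least 3.

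Homeobox genes made up most of the 10 most covered genes. Replicated peaks covered all of the 10 kb around the starts of Hmx1, a homeobox gene of the eye and sensory ganglia, and Insl3, which encodes a peptide hormone. Over the same window they covered 99.5% at Cdx2, a regulator of gut and posterior fate, and from 97.9% to 99.2% at Hoxd11, Hoxa5, Hoxc4, Hoxb13 and Hoxb9. The others were Gfy (98.9%) and Ankrd63 (98.3%). The replicates' own peaks covered 97.9% ± 0.113 (SD, n = 2) of the window of Hmx1, 94.9% ± 6.49 of that of Cdx2 and 92.3% ± 7.50 of that of Ankrd63.

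The Hox clusters were marked over most of their length. Replicated peaks covered 94.8% of the Hoxa cluster (chromosome 6, 52155590 to 52260880), 82.6% of the Hoxb cluster (chromosome 11, 96194316 to 96368256), 95.8% of the Hoxc cluster (chromosome 15, 102921103 to 103036852) and 93.9% of the Hoxd cluster (chromosome 2, 74668310 to 74765142). By the replicates' own peaks the coverage was 91.0% ± 2.01, 76.7% ± 5.93, 92.2% ± 2.01 and 86.9% ± 3.47 (SD, n = 2 each). All 39 Hox promoters were marked, against 12.4% of other genes (Fisher's exact test, adjusted p = 8.62e-35). With the genes of each cluster counted once, 4 of 4 clusters were marked (adjusted p of Fisher's exact test = 0.0002).

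**Figure D3:**
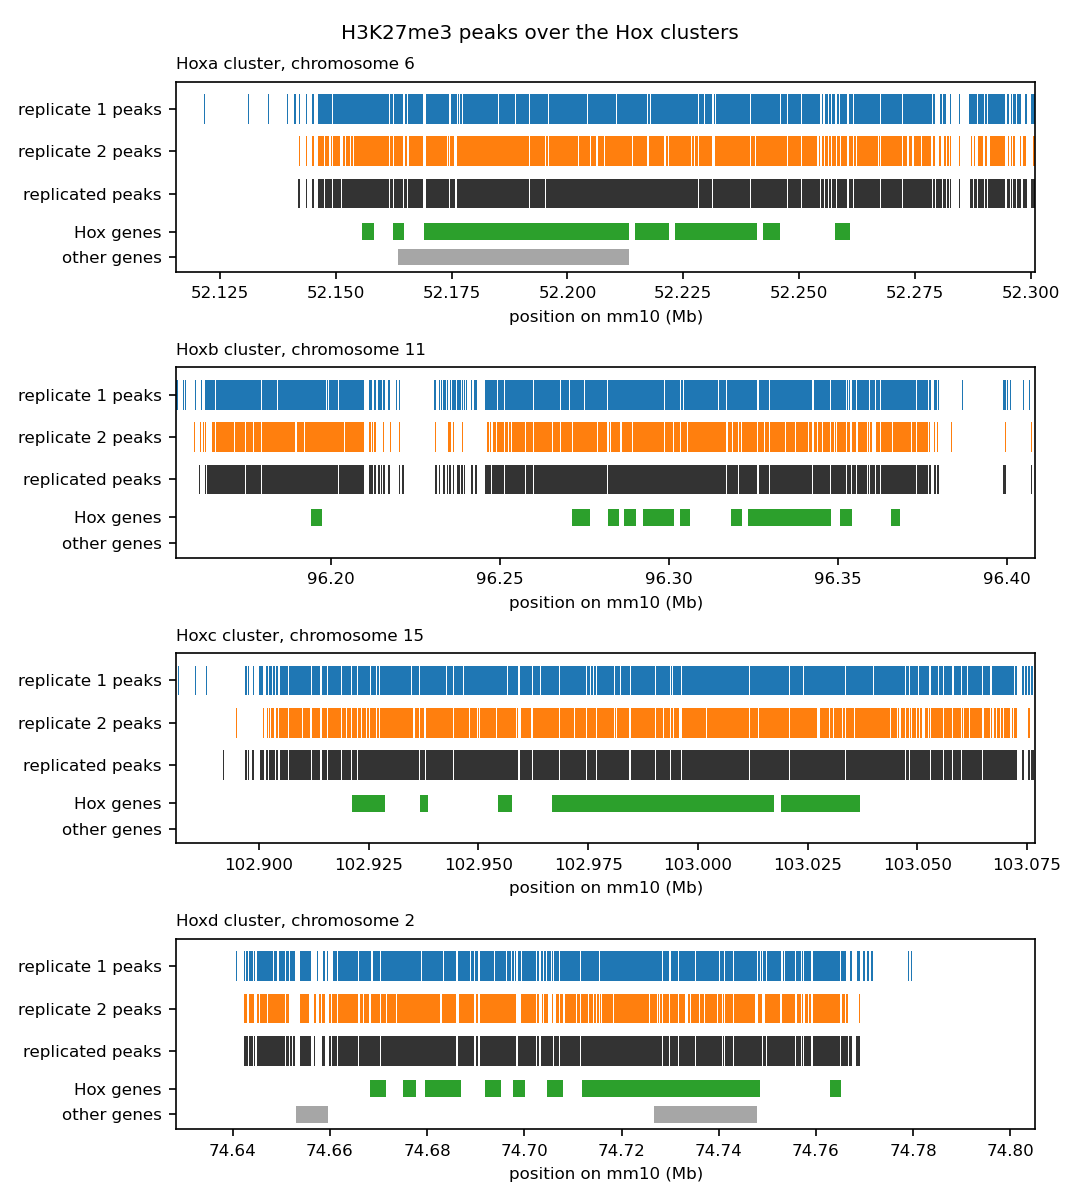
Peaks of replicate 1 (blue), replicate 2 (orange) and the replicated list (black) over the 4 Hox clusters, with Hox genes in green and other protein-coding genes in grey; the horizontal axis is position on mm10 in Mb. Coverage by replicated peaks runs from 82.6% in Hoxb, where a gap separates Hoxb13 from Hoxb9, to 95.8% in Hoxc.

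The genes that pattern the midbrain were themselves marked, in a pooled tissue whose peaks do not show which cells carried the mark. Replicated peaks marked 27 of 31 promoters in this list (87.1% against 12.4% of other genes; Fisher's exact test, adjusted p = 6.03e-20), with 28 marked in replicate 1 and 27 in replicate 2. The floor plate regulators Foxa2 and Foxa1 and the ventral gene Nkx2-2 had 91.3%, 88.7% and 91.5% of the 10 kb around their starts covered. By the replicates' own peaks these were 78.2% ± 14.1, 79.3% ± 4.45 and 83.2% ± 4.54 (SD, n = 2). The isthmic signals Fgf8 (87.7%) and Wnt1 (87.1%), with Lmx1b (84.9%), Pax2 (76.2%) and Pax5 (77.0%), were also widely covered, as was Helt (87.9%). Otx2, which defines forebrain and midbrain identity, had 15.6%, and Tal2 23.6%. En1 was marked with 50.5% covered. Its relative En2 was unmarked in the replicated list and in replicate 2 and marked in replicate 1, with 30.7% of its window covered. Lef1 (2.32%), Meis2 (2.98%) and Tcf7l2 (0%) were unmarked at the annotated 5′ end, but each had a marked transcript start elsewhere in the gene.

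Genes of transmitter identity split between marked and unmarked. Of 18 such genes, 12 were marked in the replicated list and in each replicate (66.7% against 12.5%; Fisher's exact test, adjusted p = 2.75e-07). The cholinergic pair Slc18a3 and Chat had 75.3% and 65.7% of their windows covered, and Slc17a7, a vesicular glutamate transporter, 57.4%. Slc17a6, the other such transporter in the list, was unmarked at its 5′ end (6.96% covered) and marked at another start. The serotonin transporter Slc6a4 had 51.8%. Among dopaminergic genes, Pitx3 (61.9%), Nr4a2 (47.3%), Slc6a3 (39.2%), Drd2 (39.4%) and Slc18a2 (22.2%) were marked. Th and Ddc, the enzymes of dopamine synthesis, had no replicated peak in their windows, and neither had Aldh1a1 or the serotonin enzyme Tph2. These 4 genes were unmarked at every annotated transcript start. Gad1 was unmarked at its 5′ end and marked at another start, whereas Gad2, which encodes the other GABA-synthesizing enzyme, was marked, with 39.7% covered. The replicates differed widely at Gad2 (37.2% ± 24.9, SD, n = 2) and Nr4a2 (39.8% ± 23.2).

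Regulators of other regions and germ layers carried the mark in most cases. It was at 25 of 26 forebrain patterning promoters, with Gsx2 95.8%, Six3 95.1% and Six6 93.6% covered. Hesx1, the exception, was unmarked at its 5′ end and marked at another start. The mark was also at 21 of 21 hindbrain and spinal cord genes, led by Mnx1 (96.7%), Olig3 (93.7%) and Hmx3 (93.2%). Mesoderm regulators were marked in 21 of 27 cases, with Foxf1 (95.7%), Pax1 (95.7%) and T (95.7%) most covered. Msgn1 and Myf5 had no replicated peak in their windows. Endoderm regulators were marked in 14 of 16 cases, including Neurog3 (97.0%), and not at Hnf1a or Hnf4a. The adjusted p of Fisher's exact test was 6.30e-21, 6.85e-19, 6.77e-14 and 7.18e-11 for these lists in that order. No test compared the lists with one another here.

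Families of developmental transcription factors and ligands were also marked more often than other genes. All 9 Pax genes and all 6 sine oculis homeobox genes (Six1 to Six6) were marked, as were 13 of 14 Nkx, 11 of 12 Lhx and Lmx, 5 of 6 Gata, 12 of 16 Tbx, 11 of 19 Sox, 25 of 44 Fox and 4 of 6 Irx genes. Six2 had 80.4% of its window covered, Gata6 83.8%, Tbx20 84.9% and Irx4 83.9%. Among ligands, 18 of 19 Wnt genes were marked, 11 of 21 Bmp and Gdf genes and 9 of 22 Fgf genes. Wnt10b (96.2%), Bmp7 (93.5%) and Fgf8 (87.7%) were the most covered of the Wnt, of the Bmp and Gdf, and of the Fgf genes, and Fgf1, Bmp1 and Bmp10 had no replicated peak in their windows. The adjusted p of Fisher's exact test ran from 4.92e-15 for Wnt ligands to 0.00389 for the Irx family. The Irx call was lost when at least 50% of the promoter window had to be covered (Fisher's exact adjusted p = 0.382; range over the alternatives 0.00101 to 0.382).

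Lists of cell types were marked unevenly. Only 1 of 20 pan-neuronal genes was marked, the neurofilament gene Nefl (34.4%), while Dcx and Elavl3 had no replicated peak in their windows (Fisher's exact adjusted p = 0.536). Markers of microglia and immune cells were marked at 2 of 16 genes, the complement genes C1qa (37.95%) and C1qc (43.6%), which is 12.5% against 12.6% of other genes (Fisher's exact adjusted p = 1.00). Meningeal and neural crest markers were marked at 11 of 14 genes, with Tfap2a at 87.5%, and vascular and blood markers at 8 of 20, with Flt1 at 67.1%. The adjusted p of Fisher's exact test was 6.69e-08 and 0.00255. Glial genes were marked at 8 of 14, led by Olig1 (89.3%) and Olig2 (83.8%), the regulators of oligodendrocyte fate (Fisher's exact adjusted p = 0.000148). Aqp4 and Aldh1l1, of astrocytes, had no replicated peak in their windows.

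Neural progenitor genes were marked at 8 of 18 promoters, with Neurog1 94.96%, Pax6 91.8% and Neurog2 52.6% covered. Fabp7, a radial glia gene, had no replicated peak in its window, and Ascl1 was unmarked (3.25% covered). The list passed the test (Fisher's exact adjusted p = 0.00117), and replicate 1 marked 10 of the genes where replicate 2 marked 5. The call was lost without replicate 1 (Fisher's exact adjusted p = 0.0653) and with 50% of the promoter window covered (0.122). It held with peaks that overlap both replicates, at 5 of 18 genes (Fisher's exact adjusted p = 0.0422). Over the alternatives the adjusted p of Fisher's exact test ranged from 0.000264 to 0.122.

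None of the 20 housekeeping promoters, Actb and Eef1a1 among them, was marked in the list or in either replicate, though with 12.6% of other genes marked this did not pass the test (Fisher's exact adjusted p = 0.182; 0.0436 with 2.5 kb to each side of the start, and 0.0436 to 0.677 over the alternatives). Polycomb and H3K27 demethylase genes were marked at 3 of 23 promoters, Cbx8 (69.3%), Cbx4 (31.5%) and Phf19 (20.5%). Ezh2, Eed, Suz12 and Jarid2, of the complex that writes the mark, and the demethylase genes Kdm6a and Kdm6b had no replicated peak in their windows. Bmi1 was unmarked at its 5′ end and marked at another start, with 40.3% of its window covered. The 17 germline genes, such as Asz1 and Brdt, had no marked promoter, while 2 were marked in replicate 1 and 1 in replicate 2. The adjusted p of Fisher's exact test was 1.00 for the Polycomb list and 0.178 for the germline list.

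Cell cycle inhibitors of the Cdkn2a locus were marked broadly. Cdkn2a and its neighbour Cdkn2b had 85.9% and 84.5% of their windows covered, or 83.4% ± 4.41 and 74.6% ± 4.95 (SD, n = 2) by the replicates' own peaks. Cdkn2c (30.0%) and Cdkn1a (15.0%) were marked, the latter not in replicate 2. Cdkn1b, Cdkn1c and Cdkn2d were not marked. With 4 of 7 genes marked the list passed (Fisher's exact adjusted p = 0.00784). The call was lost without replicate 1 (Fisher's exact adjusted p = 0.0509) and with a −log10 q of at least 2 (0.0510). It was also lost with 50% of the promoter window covered (Fisher's exact adjusted p = 0.0855) and among CpG-rich promoters (0.0556). Over the alternatives the adjusted p of Fisher's exact test ranged from 0.00302 to 0.0855.

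Imprinted genes were marked at 6 of 19 promoters, with Grb10 (82.4%), Dlk1 (67.1%) and Igf2 (56.4%) most covered and Cdkn1c and Igf2r unmarked (Fisher's exact adjusted p = 0.0295). This call was lost with the peaks of replicate 1 alone (Fisher's exact adjusted p = 0.125). It was also lost with pooled peaks and with promoters of 2.5 kb to each side (Fisher's exact adjusted p = 0.132 each). In these settings 6 of 19 promoters stayed marked, while the share of other genes marked rose. Among CpG-rich promoters 0 of 7 were marked, too few to show a direction (Fisher's exact adjusted p = 0.648). Over the alternatives the adjusted p of Fisher's exact test ranged from 0.00121 to 0.648. Olfactory receptor genes were the only list for which the test in its main setting called fewer marked promoters, at 1 of 1092 promoters, Olfr63, against 13.2% (Fisher's exact adjusted p = 4.35e-62). None of their promoters was CpG-rich, and reads from near-identical copies can escape unique mapping, a loss that these files cannot show.

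**Figure D4:**
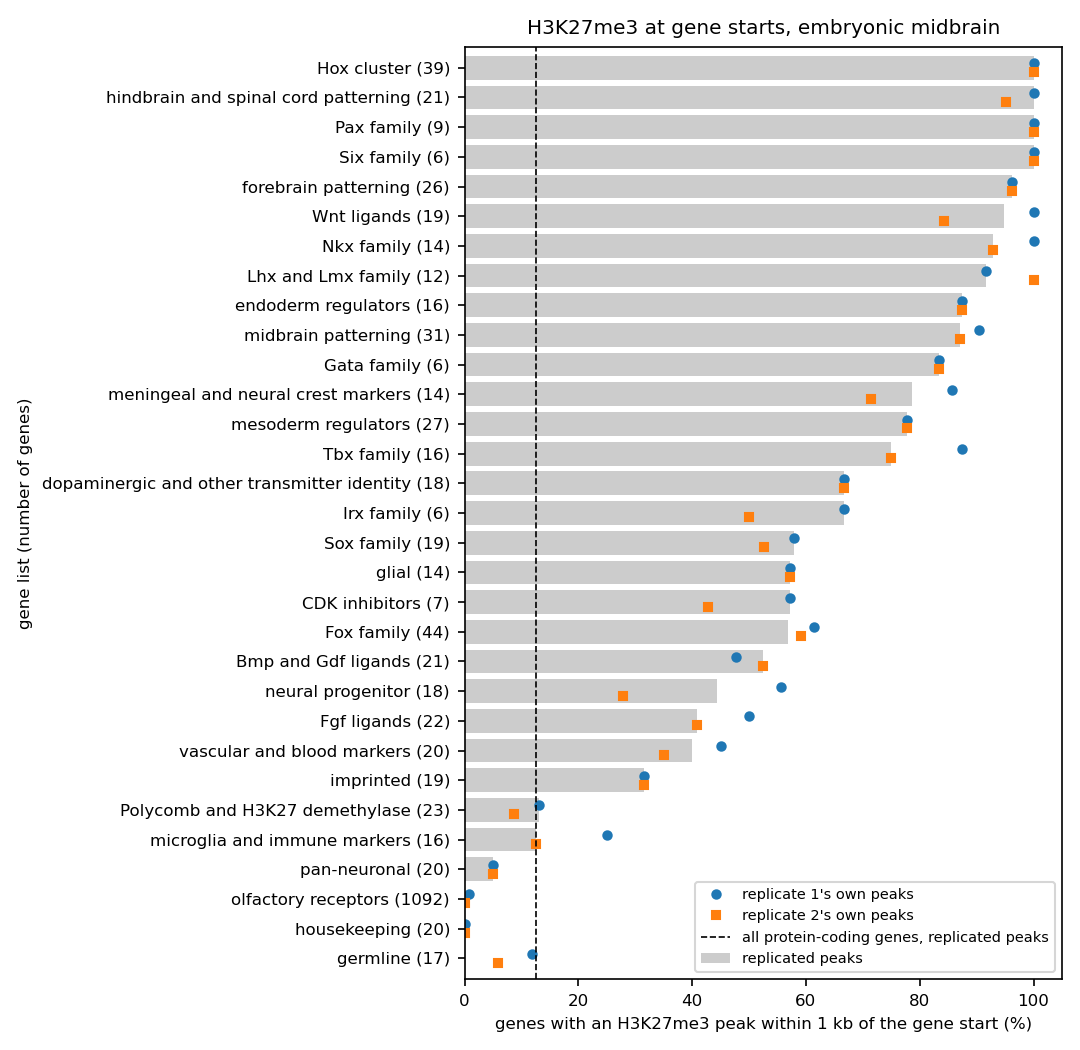
Share of genes (%, horizontal axis) with an H3K27me3 peak within 1 kb of the gene start, for each list with its number of genes; grey bars are replicated peaks, blue circles replicate 1's own peaks, orange squares replicate 2's own peaks and the dashed line all protein-coding genes (12.6%). Hox, Pax, sine oculis homeobox and hindbrain and spinal cord genes are at 100% by replicated peaks, and housekeeping and germline genes at 0%.

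At an adjusted p of 0.05, Fisher's exact test called 25 of the 31 lists as having more marked promoters than other genes and 1 as having fewer. With any annotated transcript start counted, 14 Fgf ligand genes, 5 Polycomb and demethylase genes, 2 pan-neuronal genes and 2 olfactory receptor genes were marked. The tests treat genes as the units, not samples, and neighbouring genes are not independent of each other.

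Merging replicated peaks no more than 3 kb apart gave 10146 domains, of which 249 were at least 20 kb wide. The 4 widest held the Hoxc (208 kb, chromosome 15, 102896820 to 103104706), Hoxa (187 kb), Hoxb (149 kb) and Hoxd (127 kb) genes, except Hoxb13, which lay in a separate domain of 60.5 kb. They also took in Evx1, beside Hoxa13, and Evx2, beside Hoxd13. The next was on chromosome X (152111326 to 152228749, 117 kb) and held the start of Iqsec2, a gene of synaptic signalling. Replicate 1 peaks covered 50.4% of it and replicate 2 peaks 23.3%. The sodium channel gene Scn5a, best known from the heart, had its start in a domain of 79.1 kb on chromosome 9 (119511034 to 119590097), of which the replicates covered 79.1% and 64.3%. The 10 widest domains also included the starts of Zfx on chromosome X and Shisa3 on chromosome 5. A domain of 75.9 kb within Rnf220 on chromosome 4 (117345070 to 117420999) and one of 68.0 kb on chromosome X overlapping Slc16a2 (103679082 to 103747093) held no protein-coding gene start, and these 2 genes were picked out after their values were seen. These numbers depended on the peak list and the merging distance: replicate 1 alone gave 28019 domains, 412 of at least 20 kb, and a merging distance of 1 kb left 106 that wide. With a merging distance of 10 kb the widest domain was not a Hox cluster but a region of 254.0 kb on chromosome X (151974725 to 152228749).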

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

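Restricting the replicated list to peaks that overlap both replicates, and leaving out chromosome X, were chosen after the results were seen. The overlap of the replicates kept its direction and p in all 5 alternatives, with 32.7% to 76.4% of replicate 2 peaks and 15.5% to 47.1% of replicate 1 peaks overlapped. The correlation of fold enrichment was 0.516 with a reciprocal overlap of 50% and 0.383 with a −log10 q of at least 2. The ratio for introns passed the threshold at 0.731 with promoters of 2.5 kb to each side, at 0.907 with peaks overlapping both replicates, at 0.880 without chromosome X and at 0.906 with the peaks of replicate 2 alone. It did not pass with those of replicate 1 alone, and ranged from 0.906 to 0.949 when either replicate was left out. Promoters, exons and intergenic sequence kept their direction and p in all alternatives run. Marked promoters numbered 1367 when 50% of the window had to be covered and 1782 with a fold of at least 3. With peaks overlapping both replicates they numbered 2327. Lists with more marked promoters numbered 22 to 25, and those with fewer were 2 with promoters of 2.5 kb to each side, 2 with pooled peaks and 0 among CpG-rich promoters, where no olfactory receptor could be tested. The imprinted list went from 19.04 percentage points above other genes to -14.9 among CpG-rich promoters, where 0 of 7 genes cannot show a direction. Domains numbered 22092 with pooled peaks, 6918 with peaks overlapping both replicates, and 12103 to 28019 when either replicate was left out. Those of at least 20 kb numbered 106 and 576 with merging distances of 1 and 10 kb, and 459 with pooled peaks. They numbered 194 with peaks overlapping both replicates, and 209 to 412 when either replicate was left out. The cause was not tested in any of these cases, except that a stricter rule leaves fewer promoters and a shorter merging distance leaves shorter domains by construction. No paired analysis was possible because there is 1 group. Unknown depth limits what the weaker peaks can show, since replicate 1 had 70533 peaks and replicate 2 had 33553.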

Other observations

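The gene families and the genes named with them, the comparison of X with the autosomes and the tests on how X peaks gather were chosen after results had been seen, and the other tests were set before theirs. Of 64 receptors for monoamines, acetylcholine and peptides, 36 were marked, led by the adrenergic receptor genes Adra2c and Adra2b (Fisher's exact test with Benjamini-Hochberg adjustment over 19 families, adjusted p = 5.65e-16). The same test called potassium channel genes, with 39 of 94 marked and Kcnh3 most covered (9.40e-12), collagens with 24 of 44 (1.13e-10), glutamate receptors with 9 of 28 (0.00970) and Kruppel-like factors with 7 of 17 (0.00634). It also called neural basic helix-loop-helix factors with 16 of 24 (Fisher's exact adjusted p = 3.13e-09). It called the Dlx, Msx, Pitx, Hmx, Barx, Barhl and Gsx homeobox genes with 21 of 21 (Fisher's exact adjusted p = 1.05e-18). Both of these families share members with the fixed lists, and the overlap of the other families with those lists was not counted.

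Other families were marked less often than the rest of the genes by the same test. They were vomeronasal receptors (0 of 328), Zfp zinc-finger genes (15 of 394), clustered protocadherins (1 of 56) and histone cluster genes (1 of 67). Cytosolic ribosomal proteins (2 of 76), keratins with keratin-associated genes (5 of 113) and C-type lectins with immunoglobulin-like receptors (2 of 74) were the others. Several of these sit in clusters of similar copies and are not independent. No call was made for alpha subunits of sodium and calcium channels (5 of 20) or for GABA-A and glycine receptors (3 of 23). None was made either for semaphorins, ephrins and netrins (10 of 57), proteasome subunits (3 of 40) or other protocadherins and cadherins (3 of 35). Long intergenic RNA genes had a marked 5′ end in 329 of 5854 cases (5.62%), and antisense RNA genes in 316 of 2959 (10.7%).

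Peaks of chromosome X lay at promoters less often than autosomal peaks, most of which also lay away from promoters. Of the replicated X peaks, 3.81% lay at a promoter against 16.6% of autosomal ones, and their median width was 371 bp against 486 bp. Counted by gene, 10.1% of X promoters were marked against 12.8% of autosomal ones. The replicates' own peaks gave 17.7% against 16.3% in replicate 1, and 8.54% against 12.2% in replicate 2. In replicate 1, 49.1% of X bins of 1 Mb had no peak, against 3.39% to 19.7% of bins on each autosome. Among the 169 X bins the one with Xist ranked 3 by replicate 1 peaks and 1 by replicate 2 peaks.

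As a hypothesis, the regions where X peaks gather may be a layer of H3K27me3 on the inactive X of female embryos. The share of 78.0% in the 17 fullest bins, above that of every autosome, is the pattern that prompted this hypothesis and is no test of it, so it stays open. Placement of gene starts along X also stays open: the 17 bins held 11.9% of X gene starts, 0.153 of their share of peaks, but bins picked for their peaks fall short on autosomes too (0.185 to 0.680). The embryos' sexes were mixed, so no comparison of females with males was possible, and repeats or mapping along X were not tested.

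The share of peaks on X was 13.5% in replicate 1 and 7.25% in replicate 2, and by covered length 10.6% and 4.51%. The larger number of replicate 1 peaks alone does not account for the difference in peak share. With 33553 peaks from each, the X share of peaks was 1.66 times as high in replicate 1 (95% interval 1.54 to 1.84 from resampled 1 Mb bins). X peaks run through neighbouring bins, so the bins are not independent and the interval is likely too narrow. The interval also does not cover the spread between pools. The ratio of X shares was 1.00 with 1000 peaks from each, which rests on 1 X peak in each (0.1%). It was 2.74 with 5000, 2.25 with 10000 and 1.71 with 20000. Equal numbers do not equalise depth, which is unknown and stays open. A shift of the whole X signal, such as a control library with fewer X reads could give, was to be excluded if the 8035 X peaks found in replicate 1 alone followed gene starts, and they did (rho 0.492, 0.371 to 0.596). That bound was unsound, because these peaks lay where replicate 2 also had peaks (rho 0.911 over 1 Mb bins), and a shift lifting weak regions over the threshold would do the same, so it stays open. A larger share of female embryos in replicate 1 also stays open, since shared X peaks ranked 0.925 percentile points higher there with an interval of -0.575 to 2.22, where the medians of the 19 autosomes ran from -2.30 to 0.886.

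A test of whether genes that pattern the midbrain were covered less than genes that pattern other tissues did not decide. The 31 midbrain genes had a mean covered share of 60.9% against 67.5% for 89 genes of the forebrain, hindbrain, mesoderm and endoderm lists. The difference of -6.62 percentage points had a 95% interval of -17.8 to 4.51 (permutation test, p = 0.259), and the replicates' own peaks gave -7.61 and -7.01. Lower coverage at the midbrain's own genes stays open at this precision.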
